A study of Mus musculus with 12 samples.

How the data were processed

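RNA was measured in 12 libraries of sorted mouse CD4 T cells, 3 each of Naive, Teff, Anergic and Treg cells. Per the labels' protocols, RNA was extracted with a QIAGEN RNeasy kit and made into libraries with the Takara SMARTer Stranded Total RNA-seq Pico kit. Per the series design text, the libraries were sequenced as paired-end reads on an Illumina NovaSeq. The deposited values are counts of reads per gene, unnormalised, with 1 column per library. Per the series design text, the authors made these counts with a pipeline of Trimmomatic, HISAT2, SAMtools, featureCounts and edgeR. Per the submitters' processing notes, the genome was GRCm38 (mm10), and deepTools 3.5.1.0.1 was also named. The annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping genes may have been assigned to either. The kit is for total RNA, so ribosomal RNA and small RNAs can enter the counts, and their share differs between libraries.

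The count table had 54532 entries, of which 28629 had at least 1 count and 102 names stood on several entries (207 in all), which were kept apart. No entry lacked a name, but 27 had date-like names and held 0.182% of all counts. A GENCODE annotation of GRCm38 was used for positions, and 53636 entries (98.4%) matched 1 gene in it. Column names gave each library its subset and number, and the subset came from the labels. Replicates of a subset differed by more than sampling noise (chi-square per degree of freedom 2.28 to 24.2), so no pair was treated as 1 library deposited in duplicate. Separate preparations of 1 RNA would also differ by more than sampling noise, so the check does not show separate animals. Libraries held 6909035 to 9527897 counts. The common biological coefficient of variation was 0.0764.

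The choice of comparisons, tests, gene lists, alternatives and named genes was made before the data were examined, except for 2 alternatives and the tests and gene groups that the closing section names as chosen later. Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test (glmQLFit and glmQLFTest), with TMM scaling, the filterByExpr filter and a model of subset means over all 12 libraries, in 6 comparisons. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called higher or lower, and all tests are two-sided. The standard error of a log2 fold change is its size divided by the square root of F. A fold against a subset with 0 counts was set against a floor of 3 counts over the subset's 3 libraries, and with 1 to 3 counts it is a ratio with an exact 95% interval. Intervals and floors cover counting error only. On data simulated from these libraries for Anergic against Teff, over 13036 genes, edgeR found 86% of 100 genes changed 2-fold and 99% of 100 genes changed 4-fold, with 15 false calls.

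The 29 gene lists were sort markers, anergy-associated, Treg core, naive and quiescence, pro-survival BCL2 family, BH3-only, death effectors and receptors, BATF, AP-1 and IRF, Th1 and cytotoxic, Th2, Th17, Tfh, inhibitory receptors, acute TCR response, E3 ligases and TCR attenuators, cell cycle, glycolysis, homing receptors, common gamma chain cytokine receptors, interferon response, stress response, T cell identity, CD8 T cell, B cell, plasma cell, myeloid and dendritic cell, NK and innate-like T cell, erythroid and stromal and endothelial. The lists with at least 3 tested members, 25 in each comparison, were tested with camera of limma 3.58.1 on voom log2 CPM with a preset correlation of 0.01, adjusted over the lists in each comparison. Where an adjusted p with an estimated correlation is given, the call was lost with it, and where none is given for a called list the call held. Camera with an estimated correlation held 28 of the 71 calls made with the preset one, and fry was run beside it. The count of members changed over all genes is given first, and the count adjusted over the list alone is given where it differs. The named genes in each comparison are Batf, Bcl2l11, Bcl2 and the sort markers, then the 6 highest and 6 lowest log2 fold changes (3 and 3 for Treg against Teff) among called genes with a mean of at least 10 CPM in the higher subset and no overlap of libraries. Predicted, RIKEN, ribosomal, pseudogene and receptor segment names were left out there. From each described list up to 2 risen and 2 fallen members with the smallest adjusted p were taken. Near-identical gene copies, such as Bcl2a1b and Bcl2a1d, Ly6c1 and Ly6c2, Hspa1a and Hspa1b, may share reads and are uncertain.

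Alternatives tried were DESeq2 1.42.0 and limma voom, size factors from DESeq2, scaling by total counts alone, no filter, a filter of 5 CPM in 3 libraries, fits of only the compared subsets, the replicate number as a block, each library left out in turn, and removal of 9 abundant entries, mostly ribosomal and small RNA but with the protein-coding gene Lars2 among them, without and with Anergic library 3. Gene list tests were repeated with fry, an estimated correlation, the block, other size factors, the stricter filter and each library left out. Shared profiles were compared with 20 simulated sets of unchanged groups against the same controls. The study's chromatin accessibility data were not used here, and the values of some single genes are not reported here.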

Results

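Transcript levels were measured by total RNA sequencing in 12 libraries of sorted mouse CD4 T cells, 3 from each of 4 subsets. The cells came from combined spleen and lymph nodes of untreated wild-type C57BL/6 mice with a Foxp3-GFP reporter. Naive cells had low CD44, the marker of antigen experience. Effector cells (Teff) were CD44high and lacked FOXP3, with low CD73 and FR4. Anergic cells, antigen-experienced cells in a state of functional unresponsiveness, were also CD44high and without FOXP3, but had high CD73 and FR4 and carried NRP1. Regulatory T cells (Treg) were sorted on FOXP3 and CD25. The libraries held 6909035 to 9527897 counts each, and 13393 genes had enough counts to be tested. Levels are given as TMM-scaled CPM (counts scaled to library size), mean ± SD, n = 3 per subset. The labels do not say whether the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

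Correlation of log2 CPM across genes ran from 0.982 to 0.987 between libraries of the same subset, and from 0.889 to 0.952 between subsets. A set of 9 abundant entries, mostly ribosomal and small RNA, took 28.1 to 39.6% of the counts, the most in Anergic library 3. The set, chosen after its values were seen, also holds Gm26917 and Gm42418, annotated as long intergenic RNA, and the protein-coding gene Lars2, which took 0.251 to 0.641%. Anergic library 3 also had the lowest TMM factor, 0.871. Mitochondrial ribosomal RNA took 15.3 ± 1.22% of counts in Anergic libraries, 12 ± 0.260% in Treg, 11.8 ± 0.729% in Teff and 10.3 ± 0.235% in Naive (SD, n = 3).

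**Figure D1:**
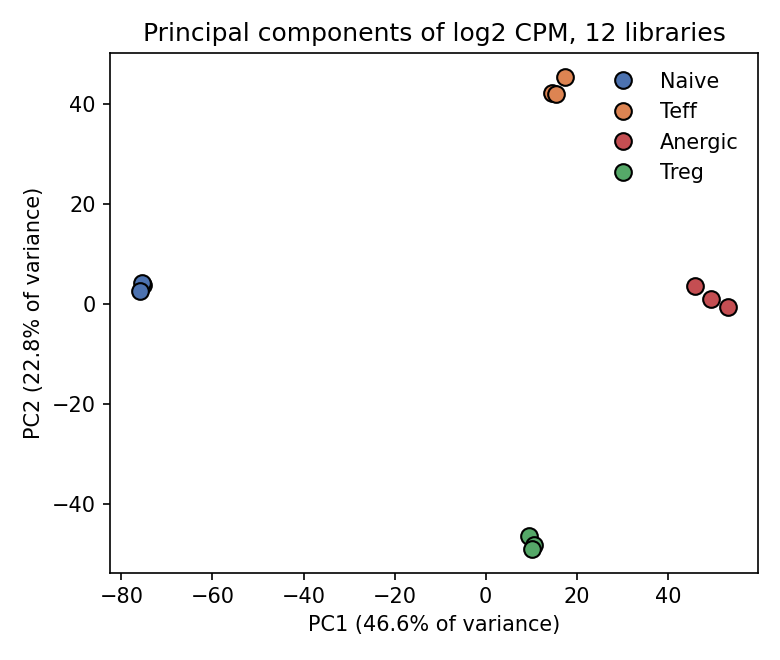
First and second principal components of log2 CPM over the 13393 tested genes, 1 point per library, coloured by subset. The first component holds 46.6% and the second 22.8% of the variance, and the 3 libraries of each subset lie together.

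The series asks how the transcription factor BATF relates to BIM, the pro-apoptotic BH3-only protein encoded by Bcl2l11, in tolerant T cells. All libraries are wild-type, so they give the levels of both genes by subset and no test of repression. Batf was highest in Anergic cells, at 61.03 ± 5.52 CPM, against 37.6 ± 8.38 in Treg, 31.7 ± 2.16 in Teff and 17.9 ± 1.65 in Naive cells (SD, n = 3). Bcl2l11 was lowest in Anergic cells, at 28.1 ± 4.01 CPM, against 40.6 ± 1.33 in Teff, 50.7 ± 4.66 in Naive and 59.2 ± 3.09 in Treg (SD, n = 3). Bcl2, the anti-apoptotic partner that binds BIM, was also lowest in Anergic cells, at 61.9 ± 8.23 CPM, and highest in Treg, at 219 ± 10.1 CPM (SD, n = 3).

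Batf in Anergic cells exceeded Teff by 1.93-fold (log2 fold change 0.95 ± 0.116 SE, adjusted p = 7.19e-07), Treg by 1.63-fold (log2 fold change 0.71 ± 0.113 SE, adjusted p = 2.46e-05) and Naive by 3.41-fold (log2 fold change 1.77 ± 0.127 SE, adjusted p = 3.44e-11). It was also above Naive in Teff by 1.77-fold (log2 fold change 0.82 ± 0.135 SE, adjusted p = 3.2e-05) and in Treg by 2.08-fold (log2 fold change 1.06 ± 0.132 SE, adjusted p = 6.26e-07). Between Treg and Teff Batf did not pass the test (log2 fold change 0.24 ± 0.120 SE, adjusted p = 0.150), although it did without Treg replicate 1 (log2 fold change 0.37, adjusted p = 0.0255; 0.0255 to 0.813 over all alternatives). Bcl2l11 was lower in Anergic cells than in Teff by 1.45-fold (log2 fold change -0.53 ± 0.0986 SE, adjusted p = 0.000178), than in Treg by 2.11-fold (log2 fold change -1.08 ± 0.0949 SE, adjusted p = 2.74e-09) and than in Naive by 1.81-fold (log2 fold change -0.86 ± 0.0975 SE, adjusted p = 9.91e-08). It was lower in Teff than in Naive by 1.25-fold (log2 fold change -0.32 ± 0.0934 SE, adjusted p = 0.00914), a call that was lost without Naive replicate 2 (log2 fold change -0.25, adjusted p = 0.0754; 0.00456 to 0.0754 over all alternatives). In Treg it exceeded Teff by 1.46-fold (log2 fold change 0.54 ± 0.0908 SE, adjusted p = 4.56e-05). Against Naive, Bcl2l11 in Treg did not pass over all genes (log2 fold change 0.22 ± 0.0898 SE, adjusted p = 0.0619) and passed without Naive replicate 2 (log2 fold change 0.29, adjusted p = 0.0348; 0.0179 to 0.268 over all alternatives). Of the 12 results for both genes, 10 passed over all genes and 11 adjusted over the list alone. In GRCm38 Batf lies on chromosome 12, 85686669 to 85709087, Bcl2l11 on chromosome 2, 128126038 to 128162547 and Bcl2 on chromosome 1, 106538178 to 106714274, and neither Batf nor Bcl2l11 shares exon sequence with another annotated gene. An opposite-strand gene covers 6.09% of the exon length of Bcl2.

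**Figure D2:**
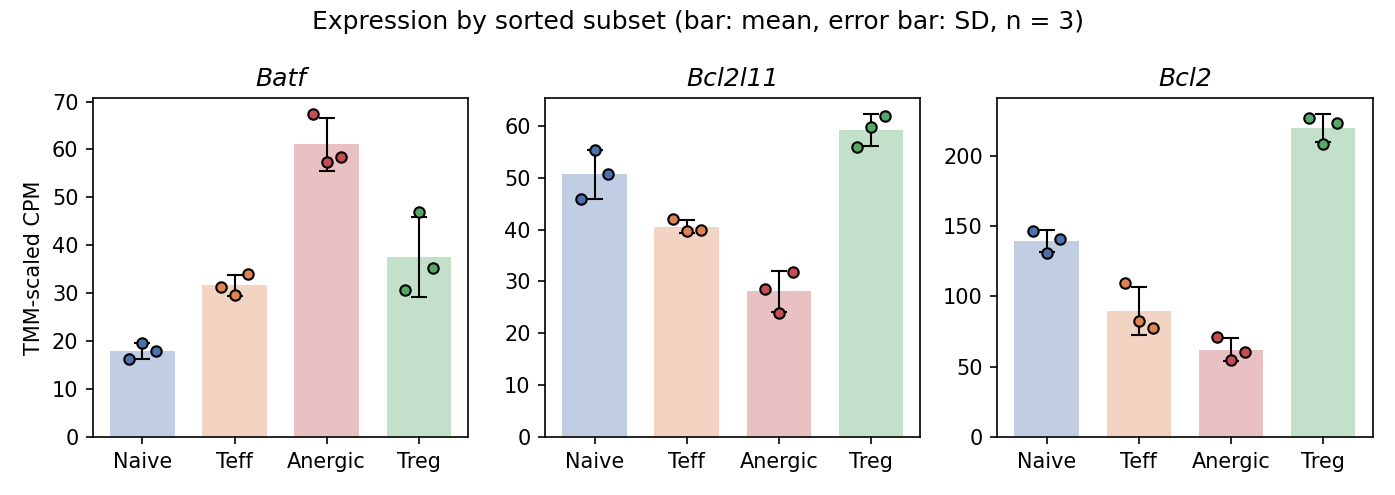
Batf, Bcl2l11 and Bcl2 in each of the 12 libraries (points) with the mean and SD of each subset (bars), in TMM-scaled CPM. Anergic libraries have the highest mean of Batf, 61.03 CPM, and the lowest of Bcl2l11, 28.1 CPM.

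Anergic cells were compared with Teff, which are also CD44high but have low CD73 and FR4. Responsiveness was not measured in these libraries. Whether follicular helper cells entered the Anergic sort was not tested either, so the differences are those of the sorted phenotypes. Of the follicular helper genes, 13 of the 14 tested members rose in Anergic cells (camera adjusted p = 1.83e-19), while of the Th1 and cytotoxic genes 13 of the 16 tested members fell (camera adjusted p = 1.54e-15). Izumo1r, which encodes the sorting protein FR4, was 5.74-fold higher in Anergic cells, Nt5e, which encodes CD73, 4.45-fold and Nrp1 5.29-fold. Foxp3 stood at 18.2 ± 2.81 CPM in Anergic and 0.733 ± 0.330 in Teff (SD, n = 3), 24.3-fold (log2 fold change 4.60 ± 0.212 SE, adjusted p = 2.84e-14) higher, although both subsets were sorted as FOXP3-negative. Cd44 did not pass over all genes (log2 fold change 0.18 ± 0.0776 SE, adjusted p = 0.0978) and passed without Anergic replicate 1 (adjusted p = 0.0286; 0.0182 to 0.537 over all alternatives). Il2ra, the CD25 chain of the IL-2 receptor, was 2.94-fold lower in Anergic cells.

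Among the genes with the largest differences, Flrt2, which encodes a membrane adhesion protein, was at least 119-fold higher in Anergic cells, and Spp1, which encodes osteopontin, 134-fold (95% counting interval 36.6 to 1108). An annotated neighbour shares 18.8% of the exon length of Spp1. Edn3, which encodes an endothelin, was 278-fold (95% counting interval 49.5 to 11021) higher. Sostdc1, a secreted antagonist of BMP and Wnt signals, reached 65.4 ± 26.3 CPM in Anergic against 0.530 ± 0.0799 in Teff, and Itgb8, a subunit of a TGF-beta-activating integrin, 59.4 ± 15.9 against 1.04 ± 0.563 (SD, n = 3). At the other end stood the NK-type lectin receptor genes Klrk1, 88.7-fold (log2 fold change -6.47 ± 0.274 SE, adjusted p = 6.87e-15) lower in Anergic cells, and Klrc1, 68.2-fold (log2 fold change -6.09 ± 0.322 SE, adjusted p = 1.13e-11) lower. Cd93, Itga1, which encodes a collagen receptor subunit, and the sulfatase gene Sulf2 were 36.7-fold, 31.8-fold and 31.2-fold lower.

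The follicular helper genes that rose included Pdcd1, which encodes the inhibitory receptor PD-1, at 126 ± 14.3 CPM in Anergic and 21 ± 0.763 in Teff (SD, n = 3). In the anergy-associated list 19 of the 28 tested members rose and 5 fell (camera adjusted p = 7.14e-12). Dtx1 and Ikzf1, members that fell, changed by -0.62 and -0.38 on the log2 scale. Among the Treg core genes 19 of the 24 tested members rose and 2 fell (camera adjusted p = 1.21e-12, and adjusted p = 0.0619 with an estimated correlation), with Cd83 16.1-fold higher in Anergic cells and Socs2, a member that fell, 3.20-fold lower. Sort marker genes recur in the anergy-associated, Treg core and follicular helper lists. Il2ra is also in the common gamma chain receptor list, Cd44 in the homing receptor list and Cd4 in the T cell identity list. Here and in the other comparisons such shared members are not independent evidence of a list's direction, nor is the sort marker list. Of the sort markers themselves 5 of the 7 tested members rose and 1 fell, or 6 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.53e-07). Of the inhibitory receptor genes 6 of the 10 tested members rose and 1 fell (camera adjusted p = 2.55e-05, and adjusted p = 0.130 with an estimated correlation). This list shares Pdcd1, Lag3, Btla, Tox and Ctla4 with the anergy-associated list, and Tigit, Entpd1 and Ctla4 with the Treg core list. Pdcd1 and Btla are follicular helper members too. In all comparisons its direction is therefore not separate evidence from theirs. Tox, a transcription factor of persistently stimulated T cells, was 3.83-fold higher and Cd160 4.30-fold lower.

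Among the Th1 and cytotoxic genes, the chemokine gene Ccl5 was 16.1-fold (log2 fold change -4.01 ± 0.153 SE, adjusted p = 1.1e-15) lower in Anergic cells and the IL-18 receptor gene Il18rap 10.05-fold (log2 fold change -3.33 ± 0.121 SE, adjusted p = 6.51e-16) lower. Of the NK and innate-like genes 6 of the 7 tested members fell (camera adjusted p = 1.53e-07). Their summed level was 227 ± 34.9 CPM in Teff, 46.1 ± 3.38 in Anergic, 42.7 ± 1.22 in Naive and 13.4 ± 0.353 in Treg (SD, n = 3). Whether invariant NKT cells in the Teff sort contribute to the Teff level stays open. In the cell cycle list 1 of the 25 tested members rose and 17 fell (camera adjusted p = 2.4e-06, and adjusted p = 0.169 with an estimated correlation), with Stmn1 1.99-fold lower and the replication helicase gene Mcm6 1.41-fold higher. Of the common gamma chain receptor genes, which include the IL-2 receptor chain Il2rb (1.80-fold lower), 5 of the 8 tested members fell, or 1 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.000265). Of the naive and quiescence genes 4 of the 20 tested members rose and 14 fell, or 5 rose and 14 fell adjusted over the list alone (camera adjusted p = 8.72e-05, and adjusted p = 0.158 with an estimated correlation), with the chromatin organiser Satb1 3.45-fold lower and Tcf7 1.46-fold higher. In the Th17 list 3 of the 6 tested members fell (camera adjusted p = 0.0122, and adjusted p = 0.169 with an estimated correlation), a call lost without Anergic replicate 1 (adjusted p = 0.0669; 0.000653 to 0.169 over all alternatives). Among interferon response genes 1 of the 20 tested members rose and 9 fell (camera adjusted p = 0.0174, and adjusted p = 0.401 with an estimated correlation), a call lost without Teff replicate 2 (adjusted p = 0.106) or Anergic replicate 1 (adjusted p = 0.178; 0.00325 to 0.401 over all alternatives).

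The lists of survival and death genes did not pass the list test. For the pro-survival BCL2 family 1 of the 6 tested members rose and 2 fell (camera adjusted p = 0.856), with Bcl2 1.45-fold and Bcl2l1, which encodes BCL-xL, 1.47-fold lower. For BH3-only genes 1 of the 7 tested members rose and 3 fell (camera adjusted p = 0.503). Beside Bcl2l11, Bbc3, which encodes PUMA, was 1.69-fold lower, and Pmaip1, which encodes NOXA, 1.69-fold higher. For death effectors and receptors 3 of the 15 tested members rose and 5 fell, or 4 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.654), with the death ligand gene Fasl 4.09-fold (log2 fold change -2.03 ± 0.142 SE, adjusted p = 5.59e-11) lower. In the list of BATF, AP-1 and IRF factors 4 of the 14 tested members rose and 5 fell (camera adjusted p = 0.515). Nfil3 was 10.9-fold and Maf 2.13-fold higher, and Bach1 1.41-fold lower. Irf4, which encodes a binding partner of BATF, was 2.64-fold (log2 fold change 1.40 ± 0.106 SE, adjusted p = 2.38e-10) higher.

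Other lists did not pass either. Of the acute TCR response genes 8 of the 19 tested members rose and 2 fell, or 9 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.0732), and the call was gained without Anergic replicate 2 (adjusted p = 0.0481) or 3 (adjusted p = 0.0297; 0.00117 to 0.347 over all alternatives). Of the homing receptor genes 6 of the 21 tested members rose and 10 fell, or 7 rose and 10 fell adjusted over the list alone (camera adjusted p = 0.0513), a call gained without Teff replicate 1 (adjusted p = 0.00960) or Anergic replicate 3 (adjusted p = 0.0196; 0.000745 to 0.347 over all alternatives). There the follicle-homing receptor Cxcr5 was 2.29-fold higher, and Cxcr6 and Ccr2 10.5-fold and 12.6-fold lower. Among E3 ligases and TCR attenuators 7 of the 20 tested members rose and 7 fell, or 8 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.863), or 3 and 7 when scaled by total counts. Rnf128, which encodes the anergy-linked ligase GRAIL, was 4.88-fold higher and Nedd4 15.5-fold lower. For glycolysis 1 of the 17 tested members rose and 6 fell, or 1 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.152), with the glucose transporter gene Slc2a3 3.15-fold lower. For Th2 genes 2 of the 6 tested members rose and 3 fell (camera adjusted p = 0.255). Of the stress response genes 1 of 13 fell over all genes (camera adjusted p = 0.609) but did not pass adjusted over the list alone. The median, mean and test of a list differed in sign for the pro-survival (median 0.20, mean 0.07, test lower), BH3-only (median 0.05, mean -0.31, test lower), BATF, AP-1 and IRF (median -0.04, mean 0.26, test higher), Th2 (median -0.51, mean 0.01, test lower) and E3 ligase lists (median 0.01, mean -0.11, test lower).

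Markers of other cells were low beside those of T cells. T cell identity genes summed to 6645 ± 228 CPM in Anergic and 5359 ± 302 in Teff (SD, n = 3), and 12 of the 16 tested members rose and 2 fell, or 13 rose and 2 fell adjusted over the list alone (camera adjusted p = 2.09e-05, and adjusted p = 0.205 with an estimated correlation), with Cd4 1.87-fold and Zap70 1.52-fold higher. B cell genes summed to 264 ± 41.5 and 211 ± 14.7 CPM, mostly Ighm. Of them 4 of the 6 tested members rose (camera adjusted p = 0.0388, and adjusted p = 0.187 with an estimated correlation). The call was lost without Teff replicate 1 (adjusted p = 0.119), Teff replicate 2 (0.180), Anergic replicate 1 (0.214) or Anergic replicate 3 (0.0945). The replicate block also ended it (adjusted p = 0.0558), with 0.00164 to 0.214 over all alternatives. Cd22, a B cell lectin gene in that list, was 2.21-fold higher in Anergic cells. Myeloid and dendritic genes summed to 37.6 ± 0.828 and 30.1 ± 2.01 CPM, and 1 of the 7 tested members rose and 1 fell, or 1 and 2 when scaled by total counts (camera adjusted p = 0.932; median 0.04, mean -0.32, test lower). Plasma cell genes summed to 50.5 ± 1.202 and 44.6 ± 3.22 CPM, CD8 T cell genes to 5.36 ± 0.435 and 4.67 ± 1.37 and erythroid genes to 0.500 ± 0.257 and 0.168 ± 0.195. The stromal and endothelial list was represented by Pecam1, which was 1.25-fold higher in Anergic cells. These 4 lists had too few tested members for the list test.

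By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1864 genes were higher and 1702 lower in Anergic than in Teff at an adjusted p under 0.05, 1181 of them by 2-fold or more. Scaling by total counts alone moved the balance to 1218 higher and 2274 lower.

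**Figure D3:**
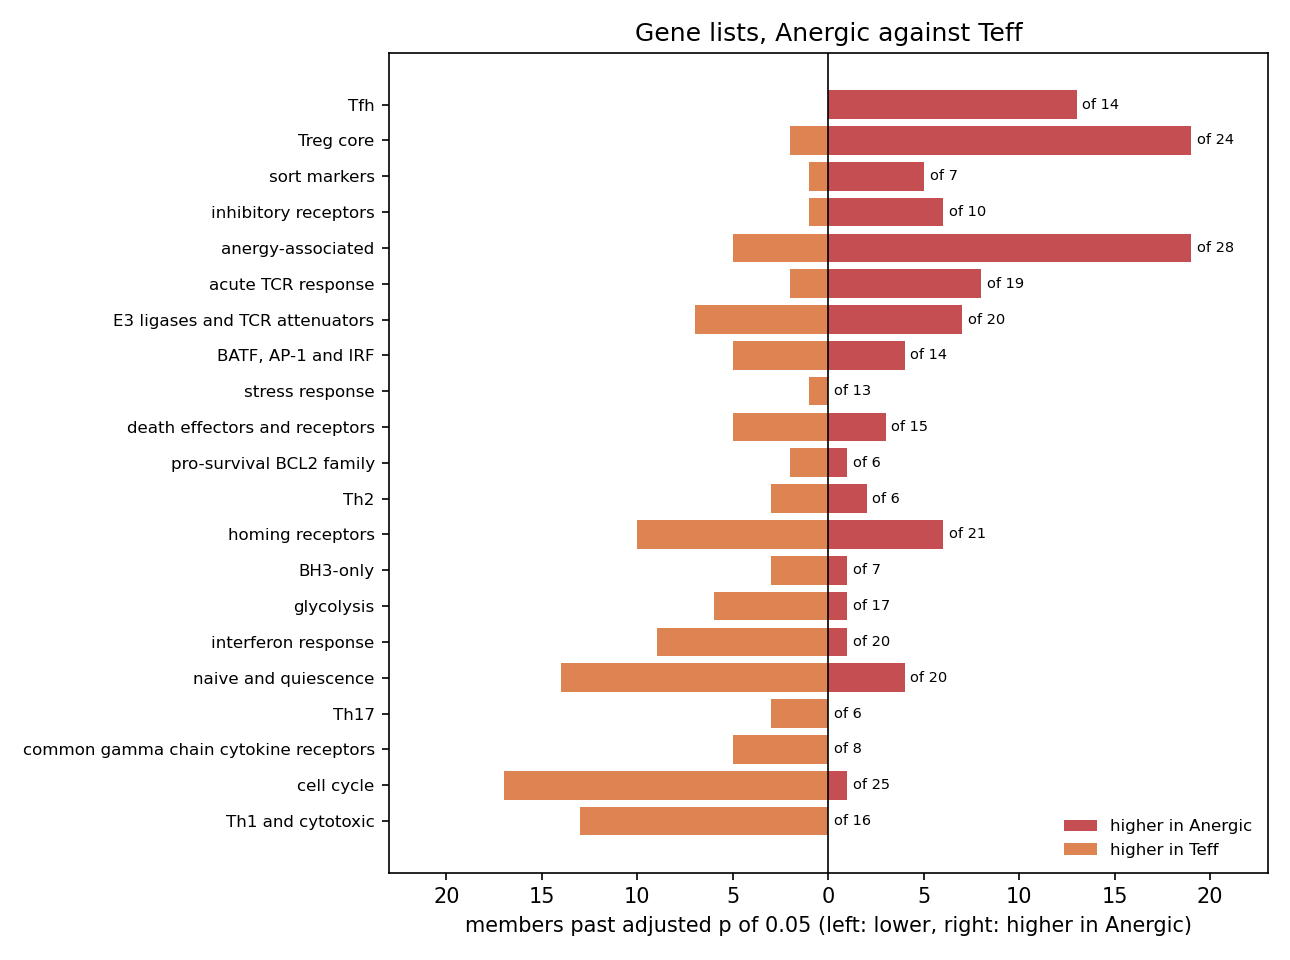
Numbers of members of tested gene lists that were higher (right) or lower (left) in Anergic than in Teff at an adjusted p under 0.05. The T cell identity list and the lists of other cell types, NK and innate-like genes included, are not shown. Follicular helper genes stand on the right (13 higher) and Th1 and cytotoxic genes on the left (13 lower).

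Anergic and Treg cells, both taken as tolerant, were compared next. They differ in FOXP3 but also in the other sort gates. Anergic cells were sorted as CD44high, while Treg were sorted on FOXP3 and CD25. The differences below therefore cannot be assigned to FOXP3 apart from CD44 state. Foxp3 was 29.8-fold (log2 fold change -4.90 ± 0.0917 SE, adjusted p = 2.15e-21) lower in Anergic cells and Il2ra 46.9-fold (log2 fold change -5.55 ± 0.132 SE, adjusted p = 2.51e-19) lower. Nt5e, Izumo1r and Nrp1 were 1.39-fold, 1.37-fold and 1.31-fold higher in Anergic cells and Cd44 2.87-fold. Bcl2 was 3.54-fold, Mcl1 1.64-fold, Bbc3 2.89-fold and Bcl2l11 2.11-fold lower. Of the pro-survival genes 2 of the 6 tested members rose and 3 fell (camera adjusted p = 0.233) and of the BH3-only genes 1 of the 7 tested members rose and 3 fell (camera adjusted p = 0.229).

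Of the follicular helper genes 14 of the 14 tested members rose (camera adjusted p = 2.25e-18). Il21, the follicular helper cytokine, stood at 52.3 ± 15.2 CPM in Anergic against 0.390 ± 0.213 in Treg (SD, n = 3), and Pdcd1 was 4.42-fold and Slamf6 3.13-fold higher. Of the Th1 and cytotoxic genes 13 of the 16 tested members rose and 2 fell (camera adjusted p = 4.74e-07), with the transcriptional regulator Id2 7.28-fold and the chemokine receptor Cxcr3 6.87-fold higher. In the anergy-associated list 18 of the 28 tested members rose and 5 fell, or 18 rose and 6 fell adjusted over the list alone (camera adjusted p = 4.74e-07, and adjusted p = 0.0873 with an estimated correlation), Nfatc1, a calcium-dependent transcription factor gene, being 3.04-fold higher and Nr4a1 2.06-fold lower. Of the Treg core genes 4 of the 24 tested members rose and 17 fell (camera adjusted p = 6.14e-12, and adjusted p = 0.0971 with an estimated correlation). Lrrc32, which encodes the TGF-beta carrier GARP, was 56.8-fold lower, and Icos 2.12-fold and Tigit 1.66-fold were higher. Of the naive and quiescence genes 3 of the 20 tested members rose and 14 fell (camera adjusted p = 4.74e-07, and adjusted p = 0.100 with an estimated correlation), with Tcf7 2.82-fold higher. Of the common gamma chain receptor genes 1 of the 8 tested members rose and 4 fell, or 2 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.00782, and adjusted p = 0.0873 with an estimated correlation). Of the T cell identity genes 12 of the 16 tested members rose and 1 fell, or 13 rose and 1 fell adjusted over the list alone (camera adjusted p = 2.13e-07, and adjusted p = 0.195 with an estimated correlation), with Cd4 2.62-fold higher.

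Inhibitory receptor genes passed (camera adjusted p = 0.0299, and adjusted p = 0.434 with an estimated correlation), as 6 of the 10 tested members rose and 3 fell. The call was lost without Anergic replicate 1 (adjusted p = 0.100), Anergic replicate 3 (0.0574) or Treg replicate 1 (0.132). It was also lost with the stricter filter (adjusted p = 0.0534), with 0.000340 to 0.434 over all alternatives. The sort markers as a list did not pass (camera adjusted p = 0.233; median 0.46, mean -0.89, test higher). Of the cell cycle genes 3 of the 25 tested members rose and 1 fell, or 3 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.954), against 3 and 6 when scaled by total counts. The proliferation marker Mki67 was 1.51-fold higher. Outside the lists, Fbn2, which encodes a fibrillin, was at least 229.7-fold and Flrt2 at least 128-fold higher in Anergic cells, and Sostdc1 579.5-fold (95% counting interval 198 to 2813) higher. Gsta4, a glutathione transferase gene, and Sorcs2 were 69.5-fold and 48.1-fold lower. Ighm, an immunoglobulin gene of the B cell list, stood at 442 ± 45 CPM in Treg and 209 ± 33.9 in Anergic (SD, n = 3), 2.11-fold lower.

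In the same edgeR test 2096 genes were higher and 2054 lower in Anergic than in Treg, 1300 by 2-fold or more. Scaling by total counts alone gave 1325 higher and 3027 lower, with the median of all genes shifted to -0.13 on the log2 scale.

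The comparison of Anergic with Naive cells sets CD44high cells with the anergy sort markers against the CD44low baseline. In Anergic cells Nrp1 was 94.4-fold (log2 fold change 6.56 ± 0.137 SE, adjusted p = 4.15e-21) higher, Izumo1r 8.51-fold (log2 fold change 3.09 ± 0.0684 SE, adjusted p = 1.29e-20), Nt5e 13.3-fold (log2 fold change 3.73 ± 0.0937 SE, adjusted p = 1.03e-19) and Cd44 9.49-fold (log2 fold change 3.25 ± 0.0922 SE, adjusted p = 1.08e-18). Foxp3 was 13.2-fold higher, from 1.35 ± 0.221 CPM in Naive cells (SD, n = 3). Bcl2 was 2.25-fold and Mcl1 1.46-fold lower.

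Of the Treg core genes 24 of the 24 tested members rose (camera adjusted p = 4.18e-14, and adjusted p = 0.0562 with an estimated correlation), among them Ikzf2, which encodes HELIOS, at 376 ± 72.2 CPM against 4.15 ± 1.26 (SD, n = 3). Of the follicular helper genes 14 of the 14 tested members rose (camera adjusted p = 2.06e-15), with Maf 31.8-fold higher. Of the inhibitory receptor genes 9 of the 10 tested members rose and 1 fell (camera adjusted p = 4.56e-06, and adjusted p = 0.109 with an estimated correlation), with Pdcd1 32.4-fold and Tigit 121-fold higher. In the anergy-associated list 20 of the 28 tested members rose and 6 fell (camera adjusted p = 2.42e-07, and adjusted p = 0.0562 with an estimated correlation), with the diacylglycerol kinase gene Dgka 1.82-fold lower. Of the Th1 and cytotoxic genes 14 of the 16 tested members rose and 1 fell (camera adjusted p = 4.56e-06), with Ifng at least 119.7-fold and Cxcr3 659-fold (95% counting interval 225 to 3199) higher. Annotated neighbours share 25.9% of the exon length of Ifng. Of the Th17 genes 5 of the 6 tested members rose (camera adjusted p = 0.00650, and adjusted p = 0.140 with an estimated correlation). Of the cell cycle genes 21 of the 25 tested members rose and 1 fell, or 22 rose and 2 fell adjusted over the list alone (camera adjusted p = 2.07e-06, and adjusted p = 0.175 with an estimated correlation), with Mki67 29.2-fold and Top2a 8.18-fold higher. Of the homing receptor genes 16 of the 21 tested members rose and 5 fell (camera adjusted p = 0.000614, and adjusted p = 0.140 with an estimated correlation), with the beta-1 integrin gene Itgb1 23.5-fold higher and S1pr1, the receptor for exit from lymph nodes, 2.56-fold lower.

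Of the naive and quiescence genes 18 of the 20 tested members fell, or 20 fell adjusted over the list alone (camera adjusted p = 2.89e-18), with Igfbp4 30.5-fold and Lef1 4.16-fold lower. All sort markers rose, 7 of 7 (camera adjusted p = 1.04e-09). T cell identity genes passed, as 8 of the 16 tested members rose and 1 fell, or 9 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0228, and adjusted p = 0.548 with an estimated correlation), a call lost without Naive replicate 1 (adjusted p = 0.0776; 0.00558 to 0.548 over all alternatives). B cell genes passed, as 5 of the 6 tested members rose (camera adjusted p = 0.0480, and adjusted p = 0.191 with an estimated correlation). The call was lost without Naive replicate 1 (adjusted p = 0.0979), Naive replicate 2 (0.0859), Anergic replicate 1 (0.112) or Anergic replicate 3 (0.0590). The stricter filter also ended it (adjusted p = 0.0962), with 0.000212 to 0.191 over all alternatives. Of the BH3-only genes 3 of the 7 tested members rose and 2 fell, or 4 rose and 2 fell adjusted over the list alone, and 2 and 2 when scaled by total counts (camera adjusted p = 0.734), with Pmaip1 8.77-fold higher and Bbc3 2.75-fold lower beside Bcl2l11. Of the pro-survival genes 4 of the 6 tested members rose and 2 fell (camera adjusted p = 0.498). Bcl2a1d, 16.99-fold higher, has near-identical copies, so its counts are uncertain. Pdlim4 and Dntt, which encodes the template-free DNA polymerase of early lymphocytes, were 86.7-fold and 35.9-fold lower. In edgeR's test 3342 genes were higher and 2851 lower in Anergic than in Naive, 2320 by 2-fold or more. Scaling by total counts alone turned the balance, with 2878 higher and 2998 lower.

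Teff were compared with Naive cells as the baseline of antigen experience, in cells sorted for low CD73 and FR4. At the RNA level Nt5e, Izumo1r and Nrp1 were nonetheless called higher in Teff than in Naive, with no overlap of libraries. The NK receptor genes Klrb1c and Klrc1, at 0 counts in all Naive libraries, were at least 286-fold and at least 170.0-fold higher in Teff, and the lymphotactin gene Xcl1 at least 106-fold. Annotated neighbours share 13.9% of the exon length of Klrb1c and 18.7% of that of Xcl1. Zbtb16, which encodes PLZF, the factor of innate-like T cells, stood at 99.7 ± 20.2 CPM against 0.481 ± 0.333 (SD, n = 3). Cd44 was 8.39-fold (log2 fold change 3.07 ± 0.0921 SE, adjusted p = 5.26e-18) higher, and Foxp3 did not pass (log2 fold change -0.89 ± 0.389 SE, adjusted p = 0.0835).

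Of the Th1 and cytotoxic genes 16 of the 16 tested members rose (camera adjusted p = 3.74e-18), with Ifng at least 184-fold and Id2 8.16-fold higher. Of the NK and innate-like genes 6 of the 7 tested members rose and 1 fell (camera adjusted p = 0.00107), their summed level being 227 ± 34.9 CPM in Teff and 42.7 ± 1.22 in Naive (SD, n = 3). Perforin, Prf1, was the member that fell, by 0.60 on the log2 scale. Of the cell cycle genes 23 of the 25 tested members rose (camera adjusted p = 4.28e-14), with Mki67 41.3-fold higher. Of the Th17 genes 6 of the 6 tested members rose (camera adjusted p = 1.5e-05), of the follicular helper genes 13 of the 14 tested members rose (camera adjusted p = 5.03e-10) and of the homing receptor genes 15 of the 21 tested members rose and 4 fell (camera adjusted p = 3.28e-06). Of the Treg core genes 19 of the 24 tested members rose and 2 fell, or 19 rose and 3 fell adjusted over the list alone (camera adjusted p = 1.34e-05, and adjusted p = 0.185 with an estimated correlation), with Ikzf2 20.4-fold higher and Gpr83 5.27-fold lower. Anergy-associated genes passed, as 16 of the 28 tested members rose and 6 fell, or 17 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.00595, and adjusted p = 0.195 with an estimated correlation), as did inhibitory receptor genes, of which 8 of the 10 tested members rose and 1 fell, or 8 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.00663, and adjusted p = 0.224 with an estimated correlation). Of the death effectors and receptors 7 of the 15 tested members rose and 1 fell, or 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00803), with Fasl 5.75-fold and Tnfsf10, which encodes TRAIL, 2.31-fold higher.

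Of the naive and quiescence genes 1 of the 20 tested members rose and 16 fell (camera adjusted p = 8.96e-16), with Igfbp4 18.03-fold lower and the IL-7 receptor gene Il7r 1.34-fold higher. Of the sort markers 5 of the 7 tested members rose, or 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 6.11e-05). Bcl2l1 was 2.55-fold higher and Bcl2 1.55-fold lower, and the pro-survival (camera adjusted p = 0.244) and BH3-only lists (camera adjusted p = 0.334) did not pass. Of the acute TCR response genes 6 of the 19 tested members rose and 8 fell, or 6 rose and 9 fell adjusted over the list alone (camera adjusted p = 0.314; median -0.19, mean 0.34, test lower), against 6 and 3 when scaled by total counts. In edgeR's test 2570 genes were higher and 2099 lower in Teff than in Naive, 1642 by 2-fold or more. Scaling by total counts alone gave 2718 higher and 1489 lower.

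Treg were compared with Naive cells as the reference for the FOXP3-positive programme. Foxp3 rose from 1.35 to 542 ± 16.2 CPM (SD, n = 3), 393-fold (log2 fold change 8.62 ± 0.134 SE, adjusted p = 3.06e-23), and Il2ra 322-fold (log2 fold change 8.33 ± 0.174 SE, adjusted p = 8.62e-21). Lrrc32, at 0 counts in Naive cells, was at least 1692-fold higher. The opioid precursor gene Penk was 991-fold (95% counting interval 177 to 39166) and the integrin gene Itgae 914-fold (95% counting interval 312 to 4432) higher. Bcl2 was 1.58-fold (log2 fold change 0.66 ± 0.0960 SE, adjusted p = 6.66e-06) and Bcl2l1 2.95-fold (log2 fold change 1.56 ± 0.101 SE, adjusted p = 8.13e-12) higher. Of the pro-survival genes 6 of the 6 tested members rose (camera adjusted p = 0.000169). Annotated neighbours, among them the same-strand gene Flicr, share 31.5% of the exon length of Foxp3, and an opposite-strand gene 14.3% of that of Penk.

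Of the Treg core genes 24 of the 24 tested members rose (camera adjusted p = 3.76e-28). BH3-only genes did not pass, as 2 of the 7 tested members rose (camera adjusted p = 0.0510), but did without Naive replicate 2 (adjusted p = 0.0287), Naive replicate 3 (0.0299) or Treg replicate 1 (0.0428), and with median-of-ratios scaling (0.0492), with 0.000194 to 0.173 over all alternatives. Pmaip1 was 9.59-fold and Bid 2.23-fold higher, and an opposite-strand gene covers 17.7% of the exon length of Bid. Of the death effectors and receptors 8 of the 15 tested members rose and 2 fell (camera adjusted p = 0.0130, and adjusted p = 0.0769 with an estimated correlation), of the cell cycle genes 21 of the 25 tested members rose, or 22 rose and 1 fell adjusted over the list alone (camera adjusted p = 4.31e-09, and adjusted p = 0.0769 with an estimated correlation) and of the anergy-associated genes 17 of the 28 tested members rose and 3 fell, or 17 rose and 5 fell adjusted over the list alone (camera adjusted p = 1.35e-05, and adjusted p = 0.0769 with an estimated correlation). Inhibitory receptor genes passed, as 8 of the 10 tested members rose and 1 fell (camera adjusted p = 2.69e-05, and adjusted p = 0.0866 with an estimated correlation), with Entpd1, which encodes CD39, 59.2-fold higher. Of the naive and quiescence genes 17 of the 20 tested members fell (camera adjusted p = 5.27e-16), with Tcf7 3.26-fold and Lef1 2.92-fold lower. B cell genes passed, as 5 of the 6 tested members rose (camera adjusted p = 0.000709, and adjusted p = 0.0723 with an estimated correlation), their summed level being 478 ± 38.9 CPM in Treg and 220.5 ± 17.2 in Naive (SD, n = 3). Of the T cell identity genes 2 of the 16 tested members rose and 8 fell (camera adjusted p = 0.00195, and adjusted p = 0.269 with an estimated correlation), from 5674 ± 364 CPM in Naive to 4794 ± 148 in Treg (SD, n = 3). In edgeR's test 2538 genes were higher and 1858 lower in Treg than in Naive, 1655 by 2-fold or more. Scaling by total counts alone gave 2922 higher and 1129 lower.

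Treg were also set against Teff, to complete the 6 pairs of subsets. Foxp3 was 725-fold (log2 fold change 9.50 ± 0.143 SE, adjusted p = 1.45e-23) and Il2ra 15.95-fold (log2 fold change 4.00 ± 0.116 SE, adjusted p = 4.97e-18) higher in Treg, and Lrrc32 at least 1894-fold. The chemokine receptor gene Cxcr6, at 214 ± 11.2 CPM in Teff and 0.827 ± 0.490 in Treg (SD, n = 3), and Id2, 17.1-fold lower, were among the genes Treg had less of. Klrc1 was at least 204-fold lower. Bcl2 was 2.44-fold and Mcl1 1.66-fold higher in Treg.

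Of the Treg core genes 23 of the 24 tested members rose (camera adjusted p = 2.79e-28), with Gpr83 78.1-fold higher. Of the Th1 and cytotoxic genes 14 of the 16 tested members fell (camera adjusted p = 1.97e-19) and of the NK and innate-like genes 7 of the 7 tested members fell (camera adjusted p = 6.64e-08), with Zbtb16 212-fold lower. Of the cell cycle genes 13 of the 25 tested members fell, or 15 fell adjusted over the list alone (camera adjusted p = 2.67e-05, and adjusted p = 0.323 with an estimated correlation), with Mki67 2.14-fold lower. Follicular helper genes did not pass, as 3 of the 14 tested members rose and 8 fell, or 3 rose and 9 fell adjusted over the list alone (camera adjusted p = 0.0864). Acute TCR response genes passed as higher, as 10 of the 19 tested members rose and 4 fell, or 11 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.0343, and adjusted p = 0.323 with an estimated correlation), although the list's mean had the other sign (median 0.39, mean -0.08). There Nr4a1 and Myc were 2.62-fold and 2.30-fold higher, and the CD40 ligand gene Cd40lg 8.22-fold lower. In edgeR's test 2006 genes were higher and 1888 lower in Treg than in Teff, 1299 by 2-fold or more. Scaling by total counts alone gave 2002 higher and 1514 lower.

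The profiles of Anergic, Teff and Treg cells against Naive cells were then set beside each other over the 13393 genes. Anergic and Teff cells shared 1942 higher and 1594 lower genes, against 641 and 447 for independent lists of the same sizes, and 132 genes moved in opposite directions. Anergic and Treg cells shared 1872 and 1290, against 633 and 396, with 214 opposite. Treg and Teff shared 1484 and 983, against 487 and 291, with 255 opposite. Across genes, which are not independent replicates, the log2 fold changes had r of 0.806 (covariance 1.30), 0.774 (1.24) and 0.668 (0.906) in the same order. All share the Naive libraries. Unchanged groups simulated 20 times against such controls gave a mean r of 0.516 (covariance 0.0285), 0.517 (0.0282) and 0.522 (0.0286). They shared a mean of 0 higher and 0.15 lower calls, 0.05 and 0.15, and 0 and 0.2, in simulations that hold no real effects. The covariances exceeded the simulated ones by 1.27, 1.21 and 0.878. With 3 Naive libraries the controls cannot be split into parts of 2, so part of the overlap in calls may come from the shared controls. The numbers for independent lists also take every gene as equally likely to be called. Whether genes with more counts were called more often in each comparison was not tested. The excess over independent lists therefore cannot be read as shared biology alone.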

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

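The removal of 9 abundant entries, mostly ribosomal and small RNA, without and with Anergic library 3, was chosen after seeing the data; the other tests were planned. Each total of changed genes, higher and lower together, stayed within 1.5 times the reported one under all alternatives. With total counts alone as the scaling, 3 one-sided counts moved by more than that, the higher genes in Anergic against Teff from 1864 to 1218 and against Treg from 2096 to 1325, and the lower genes in Treg against Naive from 1858 to 1129. With the replicate block, in the order Anergic against Teff, Treg and Naive, Teff and Treg against Naive and Treg against Teff, the counts were 3987, 4611, 6548, 5077, 4796 and 4343, and with the 9 entries and Anergic library 3 removed they were 3196, 3793, 5686, 4762, 4512 and 3994. DESeq2 gave 3000, 3587, 5573, 4030, 3844 and 3309. Pairing by replicate number was checked by the correlation of same-numbered deviations from subset means. It ran from -0.05 to 0.18, with no comparison above 0.1 in all 3 numbers. The same number correlated best in all 3 numbers in Anergic against Treg and Naive, and in Treg against Naive and Teff. Exceptions were numbers 2 and 3 in Anergic against Teff and number 2 in Teff against Naive. A weak effect shared by libraries of the same number is therefore possible, and the main model leaves it out. Libraries numbered 1 had the lowest stress response level of their subset in all 4 subsets (3109, 2912, 2752 and 2895 CPM in Naive, Teff, Anergic and Treg). They also had the lowest value of their subset on the fourth principal component, which holds 3.40% of the variance. With the replicate block Cd44 passed in Anergic against Teff (adjusted p = 0.0182), as did the stress response list in Anergic against Naive (0.0169) and Treg against Naive (0.0211) and the Th2 list in Teff against Naive (0.0334), and the B cell list in Anergic against Teff no longer did (0.0558). The block changed no other call of a named gene or list, apart from Bcl2l11 in Treg against Naive. Of 546 named results in the comparisons, 502 kept direction and call throughout, and 8530 of 8705 values did, with 166 weaker and 9 stronger and none reversed. Of 150 list results, 60 kept theirs throughout, and 1514 of 1644 values did, with 68 weaker, 61 stronger and 1 reversed. Camera called 71 of the 150 list results, 28 with an estimated correlation, 114 by fry, 73 with the replicate block and 66 to 74 with 1 library left out. The reversal was the sort marker list in Anergic against Treg, median 0.46, where fry gave the lower direction (adjusted p = 0.000743) and camera the higher. The cause was not tested.

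Bcl2l11 in Treg against Naive passed with total counts alone at 0.31 (adjusted p = 0.0179), with only both subsets in the fit at 0.22 (adjusted p = 0.0289), with the replicate block at 0.22 (adjusted p = 0.0428) and without the 9 entries and Anergic library 3 at 0.22 (adjusted p = 0.0454), all log2 fold changes. With 1 library left out it ran from 0.15 to 0.29. Bcl2l11 in Teff against Naive ran from -0.39 to -0.25 and Batf in Treg against Teff from 0.0472 to 0.37, the calls changing without Naive replicate 2 and Treg replicate 1. The cause was not tested. Depth limits genes with few counts, since a subset at 0 counts gives only a lower bound of a fold.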

Other observations

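The ribosomal protein and mitochondrial gene groups and the tests of Treg and NK cells were chosen after the result was seen. The removal of 9 entries and Anergic library 3, used in the test of ribosomal RNA load, was also chosen after seeing the data, and the other tests before their result was seen. Of the 80 ribosomal protein genes, 77 fell in Anergic against Naive (median log2 fold change -0.58), 73 fell and 1 rose in Teff against Naive (-0.55) and 44 fell and 1 rose in Treg against Naive (-0.23). In Anergic against Treg 67 fell (-0.38), in Anergic against Teff 9 (-0.04), and in Treg against Teff 58 rose (0.32). Camera gave p = 6.56e-30 in Anergic against Naive and p = 0.0618 with an estimated correlation. With an estimated correlation camera gave p = 0.0445 in Teff against Naive and 0.205 in Treg against Naive. It gave 0.111 in Anergic against Treg, 0.718 in Anergic against Teff and 0.152 in Treg against Teff. No direction turned with total counts, although 25 then fell in Anergic against Teff (median -0.14). Of the 11 mitochondrial mRNA genes 8 rose in Anergic against Teff (median 0.39, camera p = 3.07e-05, or 0.108 with an estimated correlation) and 6 in Anergic against Treg (median 0.32), or 6 and 4 when scaled by total counts. Mitochondrial ribosomal RNA also took its highest mean share, 15.3% of counts, in Anergic libraries.

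Some genes, chosen after their values were seen, had few counts. Egr2 and Hrk had 0 counts in all 12 libraries, and Kif11 had 5. Il10 had 72 counts over the Anergic libraries and 133 over the Treg libraries, and Il2 had 87 in all libraries. The annotation used for counting is not given in the sources used here, and whether the values of Egr2, Hrk and Kif11 come from it or from mapping was not tested, so they do not show that these genes were silent. The cell cycle genes Mki67 and Top2a, for comparison, stood at 144 and 83.2 CPM in Teff.

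Foxp3 stood in the Anergic libraries at 3.35% of its Treg level after scaling to library size (95% counting interval 3.04 to 3.68), although the sort excluded FOXP3-positive cells. Treg cells in the Anergic sort may be a candidate source. The test took 8 other genes with at least 20 CPM in Treg and at least 20-fold over both Naive and Teff, whatever their Anergic level. Their median Anergic level was 5.36% of Treg. Of them 2 had their own interval wholly below that of Foxp3, Gsta4 (1.37%) and Lrrc32 (1.76%), and 4 wholly above. Those above included Penk (83.9%) and Itgb8, which was higher in Anergic than in Treg (165%). Neb, also above, stood at 7.76 CPM in Anergic and 6.89 in Naive. The number below was 2, where the test asked for at least 3 and a median below the interval. It therefore does not decide on Treg cells in the Anergic sort. Treg cells like those of the Treg libraries would bring in Lrrc32 and Gsta4 at the Foxp3 share. Within counting error, such cells alone would therefore not supply all the Foxp3 counts. Genes above the interval set no such limit, since Anergic cells may express them. A partial contribution, or Treg cells with less Lrrc32 and Gsta4, cannot be told apart from expression in Anergic cells.

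Innate-like genes in the Teff libraries included Klrb1c at 38.8 CPM. NK cells in the Teff sort, where only CD4 T cells were taken, were argued against by the levels of 5 abundant NK genes, 5.57% of Klrb1c in sum: Tyrobp 0.581, Fcer1g 0.893, Gzma 0.645, Ncr1 0.0412 and Klra8 0 CPM. Whether invariant NKT cells contribute stays open. Their segment Trav11 took a share of Trav counts 1.85 times that in Naive (9 of 1828 against 7 of 2627 counts), but 8 of the 9 were in Teff replicate 1, and without it the ratio was 0.301 (1 of 1247). Traj18 took 5.64% of Traj counts in Teff against 5.34% in Naive. With so few counts, and a Traj18 share that would hide a small population, invariant NKT cells in the Teff sort cannot be told apart from other Teff as the source.

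Bcl2l11 was lower in Anergic cells than in Teff. Without the 9 abundant entries, mostly ribosomal and small RNA, and Anergic library 3 the log2 fold change was -0.64 ± 0.105 SE (adjusted p = 4.67e-05). Anergic libraries 1 and 2 still held more mitochondrial ribosomal RNA (13.88 and 15.75% of counts) than the Teff libraries (10.95, 12.3 and 12.11%). The removal therefore shows that the difference does not rest on library 3, but does not exclude ribosomal RNA load. A trend with transcript length did not account for the difference, since -0.55 ± 0.0986 SE remained after it was subtracted. A biological difference between the subsets, such as the Batf level, stays open and was not tested by these wild-type libraries.

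Each comparison has 10 splits of its 6 libraries into 3 and 3, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many calls. Counts were 3566, 4150, 6193, 4669, 4396 and 3894, in the order Anergic against Teff, Treg and Naive, Teff and Treg against Naive and Treg against Teff. The highest other split gave 0 calls by edgeR and by voom in each, and at an unadjusted p under 0.05 879, 499, 553, 810, 499 and 513. Every other split mixes both subsets in each part, so their differences widen the spread within parts. The 0 calls therefore do not measure the rate of false calls.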
